A study of Triticum aestivum with 6 samples.

How the data were processed

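RNA was sequenced from axillary bud primordia of 3-week-old bread wheat, per the labels. The samples were 3 of the wild type KN199, a wheat cultivar, and 3 of a TaD27-RNAi line, in which an RNA interference construct is directed at the wheat gene D27. The labels do not say whether the samples of a group came from separate plants or separate pools, so the p-values measure the spread between these samples only. The labels give replicate numbers but no batch, sequencing date or pairing.

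Per the file headers, the table holds a count and an FPKM value (fragments scaled to gene length and library depth) for each gene and sample. Of the count values, 33.8% are not whole numbers, so they were treated as estimated counts. FPKM values were deposited beside them and were used here only to recover a relative depth per library. The aligner, the counting tool and their versions are not given in the sources used here. The gene identifiers carry the name of the TGACv1 gene models of Chinese Spring wheat, with a chromosome arm and a scaffold but no position, so no coordinates are given. Gene symbols, descriptions and pathways come from the deposited table, which gives a symbol for 44783 genes and a description for 65228. Of the identifiers, 0 matched the locus tags, old locus tags, symbols or Ensembl identifiers of the RefSeq gene table at hand.

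The table used here has 65536 lines with its header and ends inside chromosome arm 5BL. It lists 65535 genes, 118 of them organellar, on 26 chromosome arms from chromosome 1A to 5BL. Genes on the remaining chromosomes were not analysed here, and every share or total refers to the listed genes. Total counts were 40430876, 38383013 and 34286505 in wild type replicates 1, 2 and 3, and 42886561, 48538747 and 34176114 in TaD27-RNAi replicates 1, 2 and 3.

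The deposited estimated counts were rounded to whole numbers first. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 38416 genes holding 99.92% of the counts and set aside 27119, of which 14848 had 0 counts in all 6 libraries. Libraries were scaled by TMM. The groups were compared with edgeR's quasi-likelihood F test without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The words rose and fell are used for genes past that threshold. CPM values, scaled counts, were computed from the counts and the TMM-scaled totals and are given as mean ± SD of 3 libraries. Log2 changes are TaD27-RNAi over wild type. Their standard error (SE) was computed as the absolute log2 change divided by the square root of the F statistic. The 95% intervals of log2 changes use this SE with a normal multiplier, so with 3 libraries per group they may be too narrow. The common biological coefficient of variation was 0.096 and the median SE over the tested genes was 0.128. A gene with 0 counts in 1 group was compared with a floor of 3 counts over the group, and a gene with 1 to 3 counts there was given a ratio of counts with a 95% counting interval. These bounds and intervals cover counting error only. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.

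The test was checked on simulated data for the same comparison, with 38416 genes, of which 200 were changed by these folds and a list of 100 by 1.3-fold. It recovered 52.2% of the genes changed 1.5-fold, 80.6% of those changed 2-fold and 98.5% of those changed 4-fold. It made 205 calls, of which 30 were in the list changed 1.3-fold and 21 were false. These 21 are 10.2% of the calls, above the 5% that the threshold sets. In the data 30.6% of the tested genes were called, a far larger share than was changed in the simulation. The simulated shares of recovered and false calls therefore need not hold for the data.

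The design, the 30 gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where stated. The lists were defined by word patterns matched to the descriptions or the gene symbols. They cover strigolactone biosynthesis, strigolactone signalling, bud outgrowth transcription factors, auxin response, auxin transport and synthesis, cytokinin metabolism, cytokinin response, gibberellin, abscisic acid, ethylene, brassinosteroid and jasmonate. They also cover the carotenoid pathway, cell cycle, DNA replication and histones, cytosolic ribosomal proteins, photosynthesis (leaf markers), sugar metabolism and transport, heat shock proteins, defence, cell wall growth, lignin and xylem, meristem transcription factors, MADS-box genes, RNA silencing, transposons, nitrate and phosphate nutrition, root markers, epidermis and wax, and phloem. A match in a description or symbol places a gene in a list without showing its function. The brassinosteroid list, for one, also took in chloroplast HSP90 genes with the symbol Hsp90b1. Each list was compared with all other tested genes by camera of limma, with a preset correlation of 0.01, two-sided, and adjusted over the 30 lists. Camera was repeated with an estimated correlation between the genes of a list. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Summed CPM of a list was compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

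Genes were named by a rule that took every tested D27 gene and the 10 largest changes in each direction. For the latter, the groups could not overlap, the higher group needed a mean of at least 5 CPM, and the description had to name a protein. From each list the rule took up to 2 passing genes per direction with a mean of at least 1 CPM in 1 group. A gene whose call ended when 1 library was left out was passed over or is given with that value. The copies of D14, DWARF 53-like, CCD7 and TB1, the CYP711A1 gene on 3B, the members of list directions with 5 or fewer calls, and the genes named under other observations were chosen after their values were seen. Genes are named by symbol or description and chromosome arm.

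The alternatives were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, leaving out each library in turn, limma-voom, DESeq2, a minimum log2 change of 1, camera with an estimated correlation, and fry. A scaling by the library depth recovered from the ratio of counts to FPKM was added after the data were seen.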

Results

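The series measured messenger RNA in axillary bud primordia, the young side shoots that become tillers, of 3-week-old bread wheat. It holds 3 libraries of the wild type KN199 and 3 of TaD27-RNAi, with 34176114 to 48538747 counts over the 65535 genes of chromosomes 1A to 5BL that the table used here lists. D27 is an isomerase of carotenoids at the start of the pathway to strigolactones, hormones that restrain the outgrowth of axillary buds. The comparison asks which bud transcripts differ between the RNAi line and the wild type. Within-group correlations of log CPM across genes were 0.979 to 0.987 and between-group correlations 0.959 to 0.966. The first principal component held 55.3% of the variance and separated the groups.

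The tested D27 transcripts did not differ detectably between the groups. The table lists 5 genes annotated as beta-carotene isomerase D27, of which those on 1AS and 1DS had enough counts to test. D27 on 1AS (TRIAE_CS42_1AS_TGACv1_020330_AA0076720) stood at 2.53 ± 0.674 CPM in wild type and 2.56 ± 0.0922 in TaD27-RNAi. Its log2 change was 0.01 (SE 0.23, 95% interval -0.43 to 0.46, edgeR quasi-likelihood adjusted p = 0.973). D27 on 1DS (TRIAE_CS42_1DS_TGACv1_080552_AA0249980) stood at 3.21 ± 0.274 and 2.94 ± 0.286 CPM, a log2 change of -0.12 (SE 0.19, 95% interval -0.50 to 0.25, edgeR adjusted p = 0.667). In wild type replicates 1, 2 and 3 the 1AS gene had 2.58, 3.18 and 1.83 CPM, and in TaD27-RNAi 2.53, 2.66 and 2.49. The 1DS gene had 2.90, 3.31 and 3.43 CPM in wild type and 3.20, 2.97 and 2.63 in TaD27-RNAi. The 3 genes on 1BS had 5, 0 and 3 counts over all 6 libraries. Summed over the 5 genes, the means were 5.80 ± 0.644 and 5.50 ± 0.337 CPM, a log2 ratio of -0.08 (exact two-sided permutation p = 0.6, smallest possible 0.1). The labels do not give the targeted copy or sequence, and D27 genes on later chromosomes were not analysed here. Reads from the construct could also be counted with the gene. For these reasons the values do not check the knockdown.

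**Figure D1:**
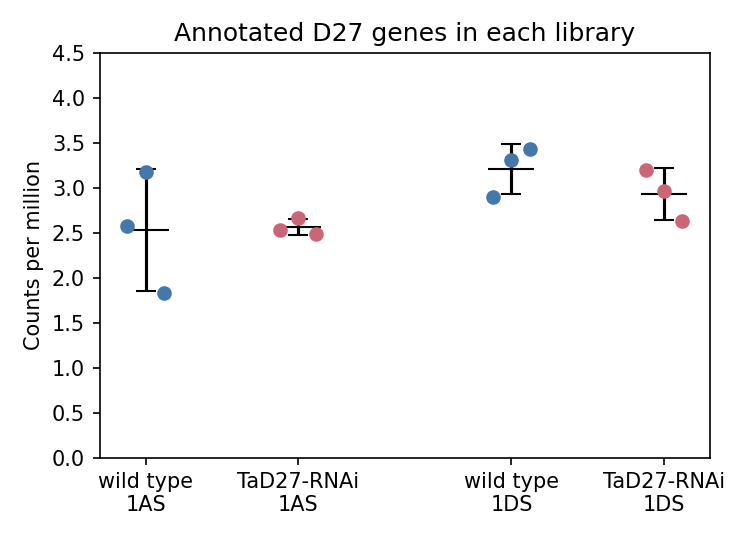
CPM of the tested D27 genes on 1AS and 1DS in each library (points), with the mean and SD of 3 libraries per group (lines). The groups overlap for both genes, with means of 2.53 and 2.56 CPM on 1AS and 3.21 and 2.94 CPM on 1DS.

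Across the tested genes, the cell cycle list was higher and the lignin and xylem list lower in the TaD27-RNAi buds (adjusted p = 0.0259 each with an estimated correlation). By camera with its preset correlation alone, the DNA replication and RNA silencing lists were higher. The lists of cell wall, wax, sugar, root, strigolactone signalling, jasmonate, abscisic acid, ethylene and auxin response genes were lower by that test. These 11 lists did not pass with an estimated correlation (adjusted p = 0.0793 to 0.22 with an estimated correlation). Of 38416 tested genes, 5244 rose and 6530 fell (edgeR quasi-likelihood, adjusted p under 0.05). The rises were smaller, with a median log2 change of 0.35 among the genes that rose and -0.64 among those that fell. At a change of at least 2-fold, 272 rose and 1996 fell. The groups did not overlap for 43.2% of tested genes, against 10% by chance. The share of tested genes that changed was 30.3% in the A, 30.7% in the B and 31.2% in the D subgenome.

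The largest rises included 2 MUS81-like genes, clpC, the kinesin gene POK2 and 2 REVEILLE genes. A MUS81-like endonuclease gene on 1BS had 0 counts in wild type and 6.86 ± 1.3 CPM in TaD27-RNAi, at least 253-fold higher (edgeR adjusted p = 3.31e-11). A clpC protease subunit gene on 2BS also had 0 counts in wild type and 5.19 ± 0.529 CPM in TaD27-RNAi, at least 198-fold higher (edgeR adjusted p = 8.04e-11). A further MUS81-like gene on 3B rose from 3.30 ± 0.487 to 24.7 ± 2.08 CPM (log2 change 2.91, SE 0.12, edgeR adjusted p = 9.82e-13). The kinesin gene POK2 on 5AS rose by 2.32 and CYP94C1 on 5BL by 2.19. RVE6 on 1AS and RVE5 on 1DS, which encode MYB-like factors of the REVEILLE family, rose by 2.09 and 1.80, the latter from 6.24 ± 0.301 to 21.8 ± 1.20 CPM (edgeR adjusted p = 4.36e-11). The remaining genes of the 10 were RAP2-3 on 2DS (2.39), RGA2 on 2DS (2.23) and RPL4A on 2AL (1.90).

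The largest falls included histone, protease inhibitor and pathogenesis-related genes. A histone H1-like gene on 5BL had 2219 counts in wild type and 3 in TaD27-RNAi, a ratio of 824 (95% counting interval 282 to 4000; edgeR adjusted p = 2.91e-14). Its 3 TaD27-RNAi counts were all in replicate 2, so the ratio rests on that library. Without it the fitted log2 change was -12.55, which rests on 0 counts in that group and is no bound. A histone H3.2 gene on 3DL fell by 7.05 on the log2 scale (SE 0.19, edgeR adjusted p = 4.99e-15), and a histone H4 gene on 3DL fell by 4.11. The wali5 gene WIP1 on 1AL fell from 28.1 ± 1.38 to 1.72 ± 0.283 CPM (log2 change -4.04, SE 0.12, edgeR adjusted p = 1.26e-14). PR1 on 4DL fell from 23 ± 0.966 to 1.79 ± 0.0754 CPM (log2 change -3.68, SE 0.12, edgeR adjusted p = 2.09e-14). ASP1 on 4BL, VSPB on 4BL, a GRF zinc finger gene on 3DS and SOT13 on 1AL also fell, with log2 changes of -3.66, -3.61, -3.41 and -3.28. PSAT1 on 4BL, at 11.8 ± 7.03 and 0.706 ± 1.22 CPM, fell by 4.28 (edgeR adjusted p = 5.34e-05), but did not pass with DESeq2 (adjusted p = 0.245, the highest over its alternatives). The lowest was adjusted p = 8.51e-101 with edgeR and no filter, which is too small to trust for 6 libraries with this spread. Why that setting gave it was not tested. All of the 72 TaD27-RNAi counts of PSAT1 were in replicate 3, and replicates 1 and 2 had 0. Its log2 change was -3.66 without wild type replicate 2 or TaD27-RNAi replicate 1 and -3.60 without TaD27-RNAi replicate 2. Without TaD27-RNAi replicate 3 the fitted value was -11.91, which rests on 0 counts in that group and is no bound. Histone, MUS81-like and RGA2-like genes have close copies, among which the authors' counting may have split reads, so the values of single copies are uncertain.

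In the strigolactone pathway, D14 and DWARF 53-like genes fell, and a single biosynthesis gene passed. Of 22 tested genes of the signalling list 12 fell, and 12 fell adjusted over the list alone. Their median log2 change was -0.26 (camera adjusted p = 0.000454; adjusted p = 0.187 with an estimated correlation). Most of the tested genes of this list are described as SMAX1-like 3 or 4, and their place in strigolactone signalling was not tested. The receptor gene D14 fell in the 3 tested genes annotated as D14, by 0.77 on 4BS (49.4 ± 1.99 to 29.0 ± 5.11 CPM, edgeR adjusted p = 2.54e-06), by 0.43 on 4AS (edgeR adjusted p = 0.00299) and by 0.33 on 4DL (edgeR adjusted p = 0.0135). Without wild type replicate 3 the 4DL copy had adjusted p = 0.0714, the highest over its alternatives, from 0.0102. DWARF 53-like genes, whose rice relative is a repressor of strigolactone signalling, fell by 0.93 on 4BS (SE 0.08, 58.8 ± 2.06 to 30.9 ± 4.71 CPM, edgeR adjusted p = 5.76e-08). They fell by 0.82 on 4AL (edgeR adjusted p = 6.91e-08) and by 0.64 on 5AL (edgeR adjusted p = 1.17e-05). The 4DS copy had a log2 change of -0.30 (edgeR adjusted p = 0.0354), which did not pass without wild type replicate 1 (0.157), wild type replicate 2 (0.101), TaD27-RNAi replicate 1 (0.12) or TaD27-RNAi replicate 2 (0.0998). The 5BL copy had -0.18 (edgeR adjusted p = 0.153). A SMAX1-like 3 gene on 4DL fell by 1.52 (SE 0.24, edgeR adjusted p = 7.37e-05). Of 8 tested biosynthesis genes, CYP711A1 on 4DL alone fell, over all genes and adjusted over the list alone. It went from 0.567 ± 0.159 to 0.106 ± 0.0524 CPM (log2 change -2.42, SE 0.64, edgeR adjusted p = 0.00714), and without wild type replicate 1 it did not pass (adjusted p = 0.0531, the highest over its alternatives, from 0.00411). The CYP711A1 gene on 3B had a log2 change of -1.57 (edgeR adjusted p = 0.0708). CCD7 had -0.57, -1.01 and -0.44 on 2AL, 2BL and 2DL (edgeR adjusted p = 0.194, 0.107 and 0.427). The 2DL copy passed without TaD27-RNAi replicate 2 (log2 change -1.14, adjusted p = 0.0393; 0.0393 to 0.924 over its alternatives). The biosynthesis list had a median of -0.50 and did not pass camera (adjusted p = 0.357; adjusted p = 0.473 with an estimated correlation). It passed with fry (adjusted p = 0.00199), which tests the genes of a list without comparing them with other genes.

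Among transcription factors linked to bud outgrowth, single SPL genes rose and another fell, and TB1 did not change detectably. The 3 TB1 genes stood below 1.1 CPM, with log2 changes of -0.27, 0.21 and -0.52 on 4AL, 4BS and 4DS (edgeR adjusted p = 0.662, 0.701 and 0.371). SPL7 on 2DL rose from 1.57 ± 0.457 to 3.6 ± 0.431 CPM (log2 change 1.20, edgeR adjusted p = 0.000583). SPL13 rose by 2.15 on 2DS, 1.84 on 2AS and 1.22 on 2BS (edgeR adjusted p = 0.0103, 0.0167 and 0.00744), and SPL7 on 2AL by 0.70 (edgeR adjusted p = 0.0406). Without wild type replicate 3 SPL13 on 2DS had a log2 change of 3.61, and without wild type replicate 1 that on 2AS had 2.67. These 4 calls each ended when single libraries were left out. SPL13 on 2DS had adjusted p = 0.0578 without wild type replicate 1 and 0.069 without TaD27-RNAi replicate 2, and on 2BS 0.0567 without TaD27-RNAi replicate 2. On 2AS it had 0.0553 without wild type replicate 2, 0.0651 without wild type replicate 3 and 0.077 without TaD27-RNAi replicate 3. SPL7 on 2AL had adjusted p = 0.173 without wild type replicate 1, 0.053 without wild type replicate 3, 0.103 without TaD27-RNAi replicate 1 and 0.114 without TaD27-RNAi replicate 2. SPL9 on 1BL fell by 0.27 (edgeR adjusted p = 0.00999). Of the 21 genes of the list these 5 rose and 1 fell, also adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.206; adjusted p = 0.369 with an estimated correlation).

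Cell cycle genes rose as a group. Of 307 tested, 134 rose and 24 fell (142 and 28 adjusted over the list alone), with a median log2 change of 0.19 (camera adjusted p = 2.48e-07; adjusted p = 0.0259 with an estimated correlation). The medians over the list were 0.207, 0.184 and 0.181 in the 3 TaD27-RNAi libraries. CYCB1-2 on 5AL rose by 1.90 (SE 0.38, edgeR adjusted p = 0.000658). CYCP4-1 fell by 2.53 on 1BL (edgeR adjusted p = 0.000122) and by 2.24 on 3B (edgeR adjusted p = 4.44e-05). Of 312 DNA replication and histone genes, 109 rose and 21 fell (115 and 23 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 2.25e-05; adjusted p = 0.22 with an estimated correlation). Histone H2AX on 4BS rose by 1.66 (edgeR adjusted p = 8.82e-06). Of 89 RNA silencing genes, 30 rose and 6 fell (35 and 7 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 2.56e-05; adjusted p = 0.0793 with an estimated correlation). DCL3B on 1DL and RDR3 on 3DS rose by 0.96 and 0.85 (edgeR adjusted p = 0.00151 and 4.36e-05), whereas argonaute genes AGO11 on 4BS and AGO12 on 5BL fell by 2.34 and 1.43 (edgeR adjusted p = 0.00416 and 0.000713). The AGO11 gene had a log2 change of -3.08 without TaD27-RNAi replicate 1.

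Lignin and xylem genes had the lowest median of the 30 lists. Of 96 tested, 55 fell and 1 rose (57 and 1 adjusted over the list alone), with a median log2 change of -0.78 (camera adjusted p = 1.82e-21; adjusted p = 0.0259 with an estimated correlation). Their summed expression went from 1511 ± 26.9 to 923.6 ± 33.3 CPM. The medians were -0.777, -0.735 and -0.88 in the 3 TaD27-RNAi libraries. The laccase gene LAC20 on 1BL and CCR1 on 1BL fell by 3.02 and 3.00 (edgeR adjusted p = 0.00017 and 0.00205). LAC20 had a log2 change of -4.49 without TaD27-RNAi replicate 2, and CCR1 had -2.40 without replicate 1 and -4.14 without replicate 3 of that group. The gene that rose, CAD7 on 2BL, had a log2 change of 0.55 (edgeR adjusted p = 0.0263) and did not pass without wild type replicate 3 (0.123), TaD27-RNAi replicate 1 (0.0791) or TaD27-RNAi replicate 3 (0.103). Of 221 cell wall growth genes, 80 fell and 15 rose (85 and 16 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 1.74e-05; adjusted p = 0.11 with an estimated correlation). The expansin gene EXPB3 on 1AL and FLA1 on 5AL fell by 1.91 and 1.86 (edgeR adjusted p = 7.78e-09 and 0.000135), and a pectinesterase-like gene on 2DS rose by 1.25 (edgeR adjusted p = 5.06e-05). Of 197 epidermis and wax genes, 73 fell and 4 rose (76 and 6 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 1.47e-06; adjusted p = 0.0793 with an estimated correlation). GDSL esterase genes of the At5g45670 type fell by 3.14 on 3B and 3.00 on 3DL (edgeR adjusted p = 0.000383 and 5.54e-05), and the 3B gene had a log2 change of -4.36 without TaD27-RNAi replicate 2. Of 106 sugar metabolism and transport genes, 41 fell and 14 rose (43 and 15 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.000468; adjusted p = 0.116 with an estimated correlation). The cell wall invertase gene CIN3 on 3DS fell by 2.34 (edgeR adjusted p = 1e-07) and the fructan exohydrolase gene 6-FEH on 2BL by 2.01 (edgeR adjusted p = 0.000733).

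The root and phloem lists had negative medians, and the photosynthesis list had a median near 0. Of 48 root marker genes, 13 fell and 3 rose (13 and 3 adjusted over the list alone), with a median log2 change of -0.20 (camera adjusted p = 0.0239; adjusted p = 0.126 with an estimated correlation). Without the filter on low counts the root list did not pass (camera adjusted p = 0.15, the highest over its alternatives, whose lowest was 0.000574 with fry). The 3 that rose were IDS3 on 1AS (0.89) and naat-B on 1AL (0.71) and 1BL (0.29), all of mugineic acid synthesis. Of 10 phloem genes, 5 fell (7 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 0.1; adjusted p = 0.22 with an estimated correlation). PP2A10 genes fell by 0.78 on 5AL and 0.73 on 5BL (edgeR adjusted p = 0.00372 and 0.00161). The other calls were further PP2A10 genes on 5AL (-0.41) and 5BL (-0.38), and PP2A1 on 3DS (-2.91), which each ended when single libraries were left out. The 5AL gene had adjusted p = 0.0971 without wild type replicate 1, 0.153 without wild type replicate 3, 0.0606 without TaD27-RNAi replicate 1 and 0.0825 without TaD27-RNAi replicate 3. The 5BL gene had 0.0737 without wild type replicate 1. PP2A1 had 0.0517 without wild type replicate 2, 0.0606 without wild type replicate 3, 0.0662 without TaD27-RNAi replicate 1 and 0.0713 without TaD27-RNAi replicate 2, and its log2 change was -2.25 without TaD27-RNAi replicate 2 and -4.81 without TaD27-RNAi replicate 3. The phloem list itself passed without wild type replicate 1 (camera adjusted p = 0.0492), with limma-voom (0.0334) and with fry (0.000149), in a range of 0.000149 to 0.22 over its alternatives. Of 100 photosynthesis genes, 10 rose and 9 fell (8 and 7 adjusted over the list alone), with a median of 0.06 (camera adjusted p = 0.4; adjusted p = 0.655 with an estimated correlation). PSBS on 3B rose by 0.97 and PSAN on 2DS fell by 0.64.

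**Figure D2:**
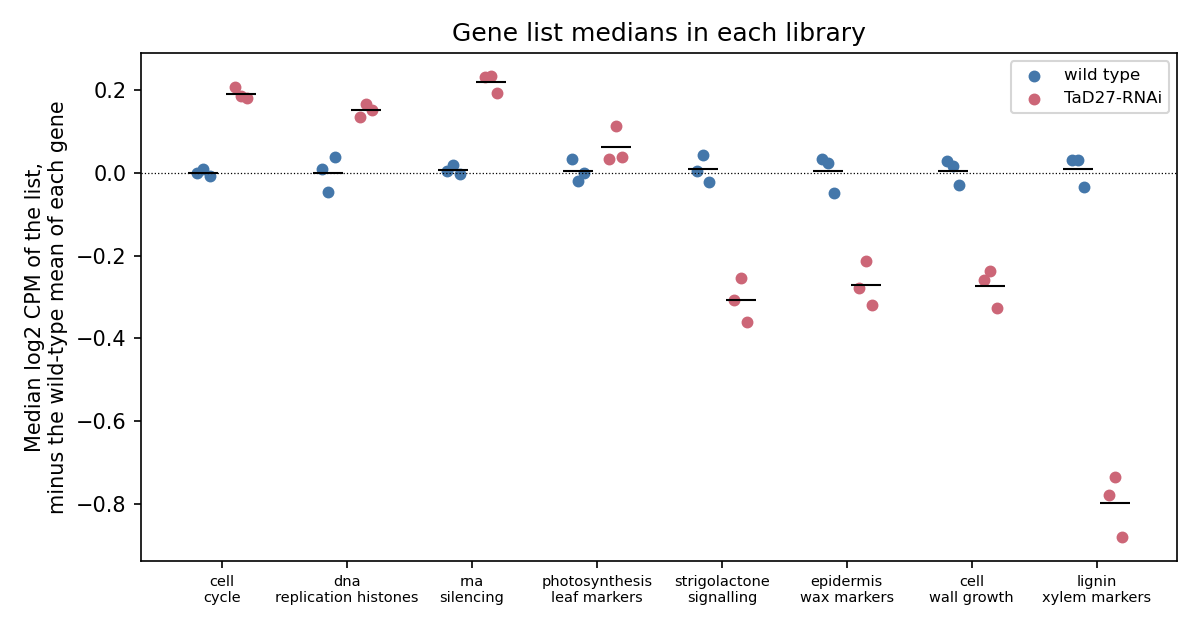
Median log2 expression of 8 gene lists in each library, relative to each gene's wild-type mean, with points for libraries and lines for group means. Cell cycle medians lie at 0.181 to 0.207 in TaD27-RNAi and lignin and xylem medians at -0.88 to -0.735.

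Of the other hormone lists, 4 passed camera, each of them lower, and these did not pass with an estimated correlation (adjusted p = 0.0793 to 0.187 with an estimated correlation). Of 77 jasmonate genes, 35 fell and 10 rose (37 and 11 adjusted over the list alone), with a median log2 change of -0.22 (camera adjusted p = 0.000298; adjusted p = 0.187 with an estimated correlation). LOX1.1 on 5BL fell from 289 ± 42.1 to 83.1 ± 7.13 CPM (log2 change -1.79, edgeR adjusted p = 4.22e-12) and TIFY10B on 5AL rose from 80.6 ± 2.86 to 156 ± 8.54 (log2 change 0.96, edgeR adjusted p = 1.29e-10). Of 207 abscisic acid genes, 66 fell and 19 rose (71 and 24 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.000781; adjusted p = 0.0793 with an estimated correlation). ASR1 on 3DL fell by 2.49 (edgeR adjusted p = 4.14e-05). Of 143 ethylene genes, 50 fell and 18 rose (55 and 24 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00392; adjusted p = 0.187 with an estimated correlation). Of 141 auxin response genes, 49 fell and 17 rose (55 and 17 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.0142; adjusted p = 0.0793 with an estimated correlation). The auxin response list did not pass without the filter on low counts (camera adjusted p = 0.0604; over its alternatives from 7.97e-05 with fry to 0.0793 with an estimated correlation). SAUR32 fell by 3.08 on 1AL and 2.08 on 1BL (edgeR adjusted p = 0.000302 and 0.000195), and SAUR19 on 2DL rose by 0.94 (edgeR adjusted p = 9.45e-05).

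The remaining hormone lists did not pass, though single genes did. Of 47 auxin transport and synthesis genes, 10 rose and 9 fell (10 and 9 adjusted over the list alone; median -0.10; camera adjusted p = 0.456). YUC11 on 5AL fell from 5.57 ± 0.707 to 0.869 ± 0.197 CPM (log2 change -2.66, edgeR adjusted p = 1.53e-08) and LAX3 on 4AL fell by 1.58 (edgeR adjusted p = 0.000633). Of 38 cytokinin metabolism genes, 7 rose and 9 fell (7 and 9 adjusted over the list alone; median -0.07; camera adjusted p = 0.456). The cytokinin dehydrogenase gene CKX4 on 3AL rose by 1.15 (edgeR adjusted p = 0.000353) and LOGL5 on 4AL, of cytokinin activation, fell by 1.31 (edgeR adjusted p = 0.00433). Of 43 cytokinin response genes, 13 fell and 5 rose, likewise adjusted over the list alone (median -0.18; camera adjusted p = 0.357). Among the 5 that rose, the response regulator gene ARR3 rose by 0.84 on 2BL and 0.68 on 2DL (edgeR adjusted p = 0.000274 and 8.75e-05), and ARR9 on 3DL by 0.35 (edgeR adjusted p = 0.00123). Of 46 gibberellin genes, 6 rose and 14 fell (7 and 14 adjusted over the list alone; median -0.33; camera adjusted p = 0.105), and the list passed without TaD27-RNAi replicate 2 (camera adjusted p = 0.0342; over its alternatives from 0.0181 with fry to 0.483). GASA3 on 1DL fell by 1.56 (edgeR adjusted p = 3.27e-09) and CIGR2 on 2BS rose by 0.54 (edgeR adjusted p = 5.72e-06). Of 32 brassinosteroid genes, 4 rose and 6 fell, likewise adjusted over the list alone (median 0.00; camera adjusted p = 0.787). Of 39 carotenoid pathway genes, 12 rose and 4 fell, likewise adjusted over the list alone (median 0.14; camera adjusted p = 0.0556). LUT2 on 3AL rose by 0.77 (edgeR adjusted p = 0.00133). The carotenoid list passed without wild type replicate 1 (0.0492), wild type replicate 3 (0.0421) or TaD27-RNAi replicate 3 (0.0334), with limma-voom (0.0334), with the stricter filter (0.0366) and with fry (0.00698), in a range of 0.00698 to 0.182 over its alternatives.

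Defence, meristem and housekeeping genes did not pass as groups. Of 761 defence genes, 156 fell and 66 rose (152 and 63 adjusted over the list alone; median -0.11; camera adjusted p = 0.111), and PR1 on 4BL fell by 4.19 (edgeR adjusted p = 4.91e-08). Of 96 meristem transcription factor genes, 14 fell and 10 rose (11 and 9 adjusted over the list alone; median -0.06; camera adjusted p = 0.791). GRF12 on 2BL rose by 0.73 and LBD39 on 4DS fell by 1.21 (edgeR adjusted p = 5.19e-05 and 1.47e-06). Of 35 MADS-box genes, 3 rose and 9 fell, likewise adjusted over the list alone (median -0.12; camera adjusted p = 0.256). Of 347 cytosolic ribosomal protein genes, 33 rose and 35 fell (25 and 17 adjusted over the list alone; median -0.01; camera adjusted p = 0.481). Of 138 heat shock protein genes, 25 rose and 31 fell (28 and 32 adjusted over the list alone; median -0.02; camera adjusted p = 0.872). Of 88 transposon genes, 12 rose and 9 fell (8 and 9 adjusted over the list alone; median 0.10; camera adjusted p = 0.381). Of 64 nitrate and phosphate nutrition genes, 11 rose and 11 fell (13 and 12 adjusted over the list alone; median -0.05; camera adjusted p = 0.755). In the heat shock, meristem and nutrition lists the median and mean were negative and the direction of the test was up. In the ribosomal list the median was negative, and the mean and the test were positive.

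Where few genes of a list moved one way, several of the calls ended when single libraries were left out. In the carotenoid list, ZEP on 2DL fell by 0.33 (edgeR adjusted p = 0.00283). PSY on 5BL had a log2 change of -2.84 (edgeR adjusted p = 0.00979) and did not pass without wild type replicate 1 (0.0552) or with DESeq2 (0.208), and its counts in TaD27-RNAi were all in replicate 2. Without that library the fitted log2 change was -7.89, which rests on 0 counts in that group and is no bound. BHY on 4DL had -0.74 (edgeR adjusted p = 0.0133) and did not pass without wild type replicate 1 (0.0686) or TaD27-RNAi replicate 3 (0.0549). VDE1 on 3B had -0.34 (edgeR adjusted p = 0.0444) and did not pass without any 1 of the 6 libraries (0.0563 to 0.24). In the cytokinin response list, ARR3 on 2AL had 0.38 (edgeR adjusted p = 0.0488) and likewise did not pass without any 1 library (0.0526 to 0.186). AHP4 on 1DL had 1.36 (edgeR adjusted p = 0.0489) and did not pass without any 1 library but wild type replicate 3 (0.0697 to 0.16). In the brassinosteroid list, the chloroplast HSP90 gene Hsp90b1 rose by 0.48 on 5AL and 0.28 on 5BL (edgeR adjusted p = 2.51e-06 and 0.000318). BRL1 on 5AL had 0.53 and did not pass without wild type replicate 2 (0.0648) or 3 (0.151) or TaD27-RNAi replicate 1 (0.107) or 2 (0.141). NOA1 on 5AS had 0.28 and did not pass without wild type replicate 2 (0.0547) or TaD27-RNAi replicate 2 (0.114). Among MADS-box genes, MADS32 on 3B and MADS50 on 5AL rose by 0.45 and 0.58 (edgeR adjusted p = 7.48e-05 and 0.00543). MADS18 on 2AS had 0.96 and did not pass without wild type replicate 1 (0.102) or 2 (0.0535) or TaD27-RNAi replicate 1 (0.0547) or 3 (0.0565). Among epidermis and wax genes, At5g55050 on 5AL rose by 0.53 (edgeR adjusted p = 0.00454). KCS2 on 5AL had 0.29 and did not pass without wild type replicate 3 (0.0712) or TaD27-RNAi replicate 1 (0.0773) or 2 (0.0998). CER26L on 2BL had 0.26 and did not pass without replicate 2 of the wild type (0.0558) or of TaD27-RNAi (0.12). At3g26430 on 2BS had 0.26 and did not pass without wild type replicate 1 (0.0517) or 3 (0.112) or TaD27-RNAi replicate 1 (0.0997).

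Over the 30 lists, camera called 13, with 3 higher and 10 lower, and 2 of these, cell cycle and lignin and xylem, also passed with an estimated correlation. Fry called 23 lists, among them 10 that camera did not call. These were the strigolactone biosynthesis (adjusted p = 0.00199), bud outgrowth (0.0322), auxin transport (0.0139), cytokinin metabolism (0.0113), cytokinin response (0.00698), gibberellin (0.0181), carotenoid (0.00698), defence (0.00698), MADS-box (0.00698) and phloem (0.000149) lists.

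**Figure D3:**
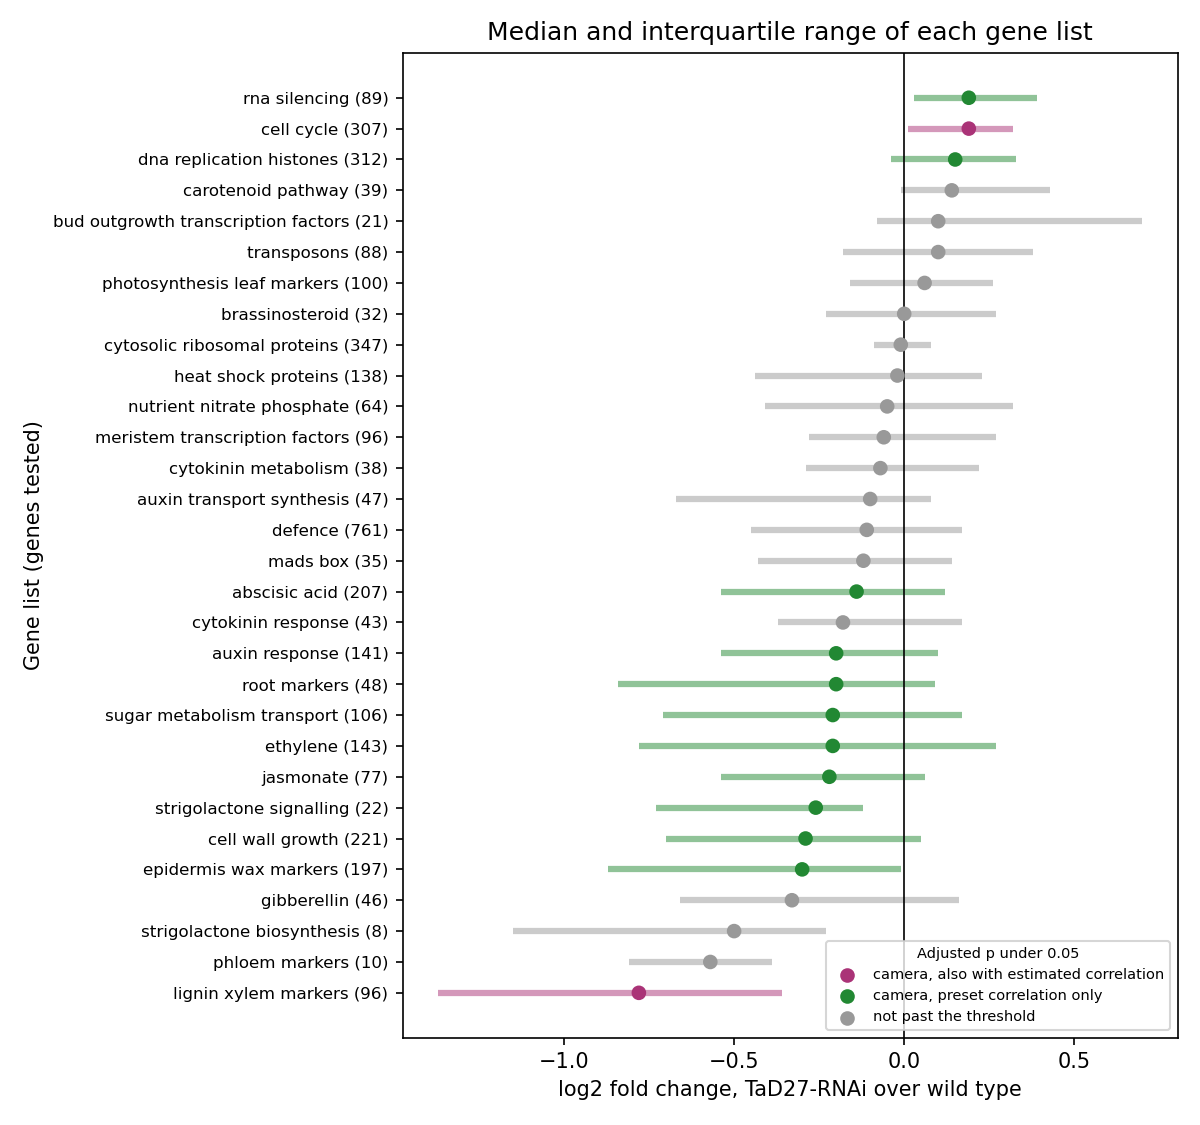
Median log2 change (point) and interquartile range (line) of each of the 30 gene lists, TaD27-RNAi over wild type, coloured by whether camera called the list and whether it also passed with an estimated correlation. Lignin and xylem lie lowest with a median of -0.78.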

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

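Of these tests, the scaling by depth recovered from FPKM was chosen after the result was seen. The counts of changed genes stayed within 1.5-fold under other scalings, filters and tools. RLE and upper-quartile scaling gave 5517 and 5695 higher and 6364 and 6291 lower genes, no filter 5547 and 6952, limma-voom 5310 and 6772, DESeq2 5356 and 6299, and the FPKM depth 5341 and 6469. These settings moved the median of all genes by at most 0.024. Leaving out 1 library gave 3729 to 4809 higher and 4907 to 5956 lower genes, the fewest without wild type replicate 1. Requiring a log2 change of 1 left 272 higher and 1996 lower, as its threshold removes small changes. Camera called 13 lists, with an estimated correlation 2, and fry 23. Fry does not compare a list with other genes, and 30.6% of the tested genes changed, so a fry call does not set a list apart from them. Why fry called more lists was not tested further. Lists called ranged from 13 to 15 when 1 library was left out. The replicate block gave 5534 higher and 6757 lower genes. Same-numbered libraries share only a number, with correlations of their deviations across genes of -0.001, 0.009 and 0.067, and wild type replicate 3 alone correlated best with its own number. With the block, WOX4 on 2DL (edgeR adjusted p = 0.0592) and AHP4 on 1DL (edgeR adjusted p = 0.0607) no longer passed, and no other call of a named gene or list changed. WOX4 also did not pass without wild type replicate 1 (0.187), 2 (0.112) or 3 (0.0527) or TaD27-RNAi replicate 1 (0.138) or 3 (0.0639), and AHP4 did not pass with no filter (0.0644). Over all alternatives, 137 values of named genes and lists no longer passed and 19 newly passed. Those that changed sign had passed no test in the main setting. The log2 ratio of the summed TaD27 transcripts was -0.132 to 0.028 when 1 library was left out. D27 on 1AS had -0.163 to 0.22, below 0 without wild type replicate 3 (-0.163) and without TaD27-RNAi replicate 2 (-0.016). RVE5 on 3AS had -0.131 to 0.049, above 0 without wild type replicate 3 (0.021) and TaD27-RNAi replicate 3 (0.049). For lists, the direction is that of the test, and the values are medians, which near 0 can differ from it in sign. The heat shock list changed direction with no filter (-0.06), with fry (-0.018), without wild type replicate 2 (0.002) and without TaD27-RNAi replicate 2 (-0.041), in a range of -0.05 to 0.018 over the left-out libraries. The brassinosteroid list changed direction with the stricter filter (-0.156) and with fry (0.003). The ribosomal list did so with fry (-0.009) and without wild type replicate 2 (-0.024, range -0.024 to 0.025), and the nutrition list with fry (-0.051). The meristem list did so with limma-voom (-0.05), with fry (-0.064) and without TaD27-RNAi replicate 2 (-0.119, range -0.119 to 0.005). The cause of these sign changes was not tested. The D27, TB1 and CYP711A1 genes stood below 4 CPM, where depth may limit their tests, which was not tested.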

Other observations

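The families, pathways and clock genes below, with the genes named from them, and the tests of tissue shares by phloem and leaf markers were chosen after the result was seen.

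The DNA repair, chromatin modifier and RNA helicase families rose beside the cell cycle genes. Among 15 families picked by description, 10 passed camera, adjusted over the 15, and 7 passed with an estimated correlation. Of 121 DNA repair and meiosis genes, 57 rose and 1 fell, with a median log2 change of 0.25 (camera adjusted p = 6.94e-12; adjusted p = 0.00792 with an estimated correlation). The words that picked this family include MUS81, whose genes were already among the largest rises, so its p-values are not independent of that choice. MSH7 on 3B rose from 21.0 ± 0.154 to 35.9 ± 1.58 CPM (n = 3 libraries per group; edgeR adjusted p = 9.73e-08) and RAD50 on 5AS rose by 0.46 (edgeR adjusted p = 1.51e-06). Of 235 chromatin modifier genes, 82 rose and 11 fell (median 0.15, camera adjusted p = 3.38e-07; adjusted p = 0.0256 with an estimated correlation). The DNA methyltransferase gene MET1B on 2AS rose from 299 ± 5.42 to 445 ± 13.8 CPM (edgeR adjusted p = 1.06e-08), and the chromatin assembly factor gene FSM on 5AL rose by 0.63 (edgeR adjusted p = 7.72e-09). Of 162 RNA helicase genes, 75 rose and 6 fell (median 0.19, camera adjusted p = 8.74e-08; adjusted p = 0.0284 with an estimated correlation). Splicing genes had a median of 0.09 (camera adjusted p = 0.0128; adjusted p = 0.0284 with an estimated correlation) with 39 higher and 18 lower of 172. Of 747 pentatricopeptide genes 37 rose and 11 fell, with a median of 0.07 (camera adjusted p = 0.0449; adjusted p = 0.123 with an estimated correlation).

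Peroxidase, aquaporin and glutathione transferase genes fell beside the lignin genes. Of 106 peroxidase genes, 56 fell and 5 rose, with a median of -0.62 (camera adjusted p = 2.74e-14; adjusted p = 0.0249 with an estimated correlation), and PER12 on 2AL fell from 34.5 ± 0.49 to 4.17 ± 0.424 CPM (edgeR adjusted p = 2.09e-14). Of 32 aquaporin genes, 16 fell and 0 rose (median -0.57, camera adjusted p = 6.71e-09; adjusted p = 0.0284 with an estimated correlation). NIP3-1 on 1BL fell by 1.88, and PIP2-1 on 2AS fell by 0.77, from 176 ± 15.4 to 103 ± 6.26 CPM. Of 100 glutathione transferase genes, 39 fell and 1 rose (median -0.47, camera adjusted p = 1.07e-07; adjusted p = 0.034 with an estimated correlation). Of 185 cytochrome P450 genes, 61 fell and 9 rose (median -0.44, camera adjusted p = 1.86e-05; adjusted p = 0.082 with an estimated correlation), with CYP73A11 on 3B and CYP98A1 on 1DL, of the lignin pathway, falling by 1.52 and 1.11. CYP90D2 on 3AS, of brassinosteroid synthesis, fell by 1.16. Of 91 NAC genes, 30 fell and 12 rose, with a median of -0.47 (camera adjusted p = 0.0177; adjusted p = 0.123 with an estimated correlation), and NAC71 fell by 0.75, 0.90 and 0.63 on 4AL, 4BS and 4DS. MYB, WRKY, bHLH, receptor kinase and subtilisin genes did not pass (camera adjusted p = 0.426, 0.481, 0.136, 0.481 and 0.164).

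Pathway terms of the table were tested in each direction. Of 116 pathways tested per direction against the 8034 tested genes with a pathway (hypergeometric test, Benjamini-Hochberg adjusted, genes not independent), 16 held more of the higher and 26 more of the lower genes than expected. DNA replication held 65 higher of 129 genes (21.8 expected, adjusted p = 1.29e-16), homologous recombination 62 of 137 (adjusted p = 2.94e-13), aminoacyl-tRNA biosynthesis 56 of 121 and RNA transport 117 of 357 (adjusted p = 1.24e-12 each), mismatch repair 50 of 110 (adjusted p = 4.35e-11) and ribosome biogenesis 65 of 186 (adjusted p = 2.43e-08). Phenylpropanoid biosynthesis held 144 lower of 286 (51.3 expected, adjusted p = 3.88e-35), plant hormone signal transduction 131 of 359 (adjusted p = 3.67e-16), starch and sucrose metabolism 108 of 332 (adjusted p = 1.1e-09), flavonoid biosynthesis 24 of 37 (adjusted p = 7.63e-09) and benzoxazinoid biosynthesis 9 of 10 (adjusted p = 1.82e-05).

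Of 22 tested genes with clock-related words in their description, 10 fell and 2 rose, and the circadian rhythm pathway held 20 lower and 2 higher of 59 genes (hypergeometric adjusted p = 0.0129 for the lower genes and 1 for the higher). The 22 leave out RVE6 on 1AS, described as ASG4, which rose by 2.09 (edgeR adjusted p = 2.45e-09). The genes of the 22 that rose were RVE5 on 1DS (by 1.80) and on 3DS (by 1.66; edgeR adjusted p = 4.36e-11 and 5.74e-06), while RVE5 on 3AS had -0.06 (edgeR adjusted p = 0.821) and the LHY gene RVE2 on 3DS had 0.03 (edgeR adjusted p = 0.72). PRR37 on 2DS fell by 1.45 (edgeR adjusted p = 0.000171), and PRR73 fell by 0.47, 0.33 and 0.30 on 4AS, 4BL and 4DL (edgeR adjusted p = 0.000146, 0.000847 and 0.000998). The labels give no time of day for the sampling, so an hour of sampling that differed between groups was not tested.

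In the split by group, 5244 genes were higher and 6530 lower. Of the 10 ways to divide the 6 libraries 3 against 3, 1 gave as many, the real one, and each other split called 0 genes in either direction with edgeR, with 339 to 1193 at an unadjusted p under 0.05, and no other tool was run on the splits. Every other split mixes the groups, which widens the spread it tests against. A set of 10 splits is too few for a share under 0.05.

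The opposite movement of cell cycle and lignin genes, a gap of 0.97 between their median log2 changes (95% bootstrap interval over genes 0.78 to 1.18), was set against technical explanations and tissue shares. That interval treats genes as independent and leaves out the spread between libraries, so it may be too narrow. Library scaling moves every gene alike and leaves this gap as it is. Gene length, taken from the ratio of counts to FPKM, was related to log2 change across genes (Spearman rho 0.147, genes not being independent replicates). After the length trend was removed the gap was 0.9, or 92.8% of its size, which argues against length as its whole cause. A larger share of green leaf in the wild-type samples would have lowered the photosynthesis genes in TaD27-RNAi. Their summed CPM was 1549 ± 23.6 in wild type and 1536 ± 45.6 in TaD27-RNAi. The log2 ratio was -0.012 (standard error 0.028, from the SDs of 3 libraries per group), which argues against a larger share of green leaf only. Leaf tissue with little photosynthesis gene expression would escape this test. The summed epidermis and wax genes had a log2 ratio of -0.21, and the tissue behind it was not tested. A larger share of vascular tissue in the wild-type samples stays open and may account for part of the gap. Phloem genes are another vascular list, with 10 tested genes and 0 in other lists. Their summed CPM had a log2 ratio of -0.53 (standard error 0.026, found likewise). It went from 34.94 ± 0.304 to 24.21 ± 0.734 CPM (exact permutation p = 0.1, the smallest possible). Lists of other kinds also had low ratios, such as strigolactone signalling (-0.38), ethylene (-0.31) and jasmonate (-0.31), while RNA silencing had 0.27. A negative ratio is thus not particular to vascular lists. The most abundant gene of the phloem list, a PP2A10 gene on 5BL, had 10.9 ± 0.456 and 8.35 ± 0.291 CPM. A younger or more actively dividing bud in the RNAi line, an effect of the construct and a difference in how the buds were cut out also stay open, as untested.

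Among all listed genes, taken before the filter, 8 had at most 3 counts over 1 group and a mean of at least 1 CPM in the other. Those with the counts in TaD27-RNAi were the MUS81-like gene on 1BS, clpC on 2BS, WRKY41 on 1BL and a gene on 4AL with no named product. Those with the counts in wild type were the histone H1-like gene on 5BL, a glycine-rich cell wall gene on 3AS, an xP2-like gene on 2AL and GBF1 on 4AS. The gene on 4AL (1.19 ± 2.05 CPM) had all of its 172 counts in TaD27-RNAi replicate 2 and 0 in the other 5 libraries, so it was not on in the group as a whole. GBF1 (1.07 ± 1.02 CPM) had 0, 46 and 69 counts in wild type replicates 1, 2 and 3. The filter asked for enough counts in 3 libraries, so the 4AL gene and GBF1 were not among the tested genes. The other 6, which were tested, had counts in each library of their higher group. The real split gave 8 such genes, as 1 of 10 splits, and the highest other split gave 3, with too few splits for a share under 0.05. A few chromosome segments that differ between the lines may give such genes. The 8 genes lay on 8 arms, and 0 pairs shared a scaffold. The comparison with random gene sets took the 6 tested genes, and 9997 of 10000 random sets of like expression also gave 0. The outcome set beforehand as speaking against segments, no more pairs than in random sets, was met. This test could hardly give another outcome. Reads that moved between copies are a further candidate. For 25% of the 8 genes (2 of 8, 95% exact Clopper-Pearson interval 3.2% to 65.1%), the other genes with the same description moved the opposite way. They did so by at least 0.5 of the change. For the xP2-like gene they moved by 25.2 times its change, more than its own reads could make up, and for GBF1 by 1.54 times. For the remaining 6 of the 8 they moved the same way, marked by a negative sign. The MUS81-like gene had -4.91 and the histone H1-like gene -7.57. The interval leaves this explanation open for the 8 genes. Differences between the lines that arose in transformation or tissue culture were not tested.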
